A study of Mus musculus with 6 samples.

How the data were processed

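Gene expression was measured by RNA sequencing in 6 libraries of mouse MLL-AF9 leukaemia cells, 3 with induced deletion of Chaf1b (KO) and 3 vehicle controls (WT), grouped by the genotype in the sample labels. Per the labels' protocols, stranded poly(A) libraries were made from DNase-treated column-purified RNA and sequenced as paired-end reads of 100 bp to about 120 M reads per sample. Per the submitters' processing notes, Trim Galore 0.4.2, cutadapt 1.9.1, STAR 2.6.1e and featureCounts 1.6.2 were used with the mm10 build. The gene annotation, the strand setting of the counting and the step that made TPM from counts are not given in the sources used here. The deposited values are TPM per gene symbol, 1 value for each of 35869 symbols in every library, rounded to 1 decimal; the 6 libraries' sums lie between 999924 and 999935. TPM divides by transcript length and by the library's total, so a rise of abundant transcripts lowers all others, and it keeps no depth, so the depth per sample and counting error are unknown. The header of WT replicate 1 carries a note on a replacement that the other 5 headers lack; its meaning is not given in the sources used here.

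Since the files hold no counts, no count model was used. Genes with at least 1 TPM in at least 3 of the 6 libraries, in any group, were kept (13575; 22294 were left out). KO was compared with WT on log2(TPM + 1) in limma 3.58.1 (R 4.3.3), with genotype as the only term, eBayes with a mean-variance trend, two-sided tests and Benjamini-Hochberg adjustment over all kept genes, calling genes at an adjusted p under 0.05. Every fold change is on the log2(TPM + 1) scale, which understates changes of weakly expressed genes. Each TPM is given as mean ± SD of 3 libraries. For Chaf1b and Trim13 an exact two-sided permutation test of the TPM values was added, which cannot go below 0.1 with 3 against 3 libraries.

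Genes named in the text followed a rule fixed before the data were examined: Chaf1b, Trim13, Chaf1a and Rbbp4; the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among genes with an adjusted p under 0.05, a mean of at least 5 TPM in the higher group, no overlap of KO and WT values and a symbol that is not a predicted or clone-derived model (Gm with digits, Rik, AC, AL and BC clone names, LOC, mt- and -ps symbols); and, for each list, up to 4 members with the smallest adjusted p in the direction of the majority and up to 2 in the other direction. Fewer than 5 called genes in a direction would have been filled with genes by unadjusted p, which was not needed. Ly6g, Cxcr2, Ngp, Olfm4, Chil3, Dleu2, Kcnrg and Cyp2a4 fall outside this rule and were chosen after their values were seen, as were the genes named under other observations. Some genes that the rule selects are not reported here.

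The 26 lists, also fixed beforehand, were CAF-1 and histone chaperones, p53 target genes, DNA replication and S phase, G2 and mitosis, DNA damage repair, replication-dependent histones, primary granule genes, late granulocyte genes, monocyte and macrophage genes, the MLL-AF9 and stem cell programme, myeloid transcription factors, interferon-stimulated genes, Bcl-2 family and caspases, ER stress and amino acid response, NF-κB target genes, oestrogen response, ribosome biogenesis, immediate early and heat shock genes, and markers of erythroid cells, megakaryocytes, mast cells and basophils, eosinophils, dendritic cells, B cells, T and NK cells, and stromal and endothelial cells. Lists with at least 5 tested members (25) were tested with camera at a correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Some genes are in several lists.

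Gene positions and classes came from the RefSeq table for GRCm38.p6, the assembly that mm10 names; 32401 of the 35869 symbols matched (92.9% of those tested), and older symbols of named genes were matched through unique synonyms. Exon counts came from GENCODE M21 on the same assembly. No library was left out of the main comparison, and at most 8.48% of tested genes had identical TPM in 2 libraries of a group, so none was counted as a duplicate.

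The test was checked on simulated data for this comparison: 200 of 13575 genes were changed, all with a mean of at least 5 TPM. The noise had the size limma estimated and was drawn independently for each gene and library. No simulated library stood apart as KO replicate 1 and WT replicate 1 do, so the shares found may not carry over to these data. It recovered 70.1% of genes changed 1.5-fold, 92.5% of those changed 2-fold and 100% of those changed 4-fold, with 10 false calls (5.41% of calls). The list test called the 1 shifted list of 21 and 0 of the unshifted ones. Genes of a simulated list did not vary together, so this could not show false list calls that come from correlated members. Alternatives were other pseudocounts (0.1, 0.5 and 5), no filter, a mean of at least 5 TPM, median-ratio scaling, quantile normalization, eBayes without the trend or robust, the replicate number as a block, each replicate left out in turn, a fold threshold and no predicted gene models. Leaving out KO replicate 1 and WT replicate 1 together and leaving out microRNA and small nucleolar RNA genes were chosen after seeing the data. Figures were drawn with matplotlib.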

Results

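Polyadenylated RNA was sequenced from mouse acute myeloid leukaemia cells transformed with a retrovirus carrying MLL-AF9, a fusion oncogene of human leukaemias. The cells carried floxed alleles of Chaf1b, which encodes a subunit of the chromatin assembly complex CAF-1, and CreERT2, a recombinase that enters the nucleus when an oestrogen receptor ligand is added. The 3 knockout (KO) libraries came from cells given β-estradiol and the 3 control (WT) libraries from the same kind of floxed, CreERT2-carrying cells given ethanol vehicle, with RNA taken 48 hours after induction. Each library listed 35869 genes in TPM, transcript abundance corrected for length and scaled to a common total. The labels give about 120 M reads per sample, but TPM keeps no record of depth, so the depth behind each value is unknown. The labels do not say whether the replicates were separate cultures or clones, and the p-values therefore measure the spread between these samples, which may be technical. Since all KO cells and no WT cells received β-estradiol, the comparison holds the ligand and the deletion together.

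The first question was whether the targeted gene was lost. Chaf1b (mm10 chromosome 16, 93883900 to 93906115) was listed at 17.7, 14.4 and 14.2 TPM in KO replicates 1, 2 and 3, against 48.6, 49.0 and 50.6 TPM in WT replicates 1, 2 and 3. The KO mean of 15.4 ± 1.97 TPM (SD, n = 3) was 31.2% of the WT mean of 49.4 ± 1.06 TPM (SD, n = 3). On the log2(TPM + 1) scale Chaf1b fell by 1.62 (SE 0.09, limma adjusted p = 0.0058), and the exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. Which exons were floxed is not given in the sources used here, and the gene-level values count reads of the whole gene. Chaf1a, the large subunit of CAF-1, was at 165 ± 7.22 TPM in KO and 176 ± 9.30 TPM in WT (limma adjusted p = 0.27), and Rbbp4, the histone-binding subunit, at 234 ± 3.02 and 226 ± 3.52 TPM (limma adjusted p = 0.37). Without KO replicate 3 the adjusted p of Chaf1b was 0.070 (log2 fold change -1.57), and over all alternatives run it lay between 0.00021 and 0.070.

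**Figure D1:**
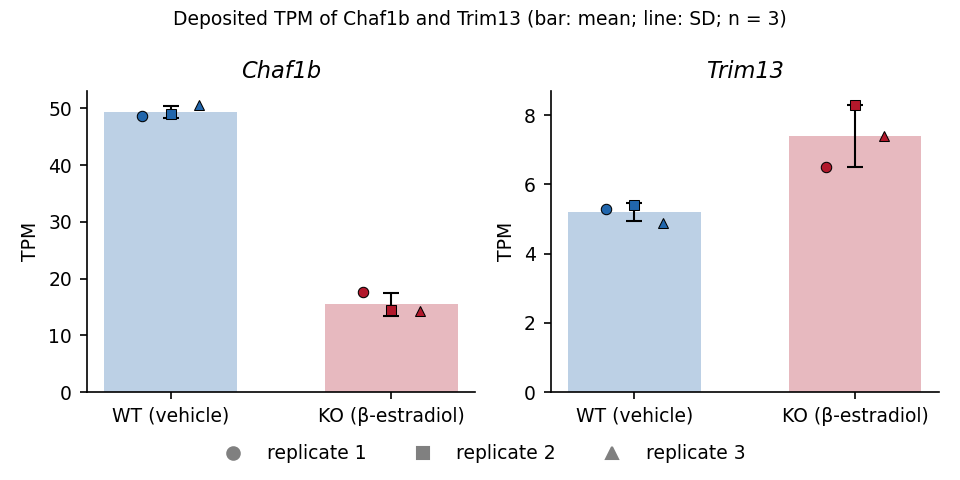
TPM (vertical axes, starting at 0) of Chaf1b and Trim13 in the WT and KO libraries, with bars at the mean, lines for the SD (n = 3) and 1 symbol per replicate. Chaf1b lies between 14.2 and 17.7 TPM in KO and between 48.6 and 50.6 TPM in WT, and Trim13 between 6.5 and 8.3 TPM in KO and between 4.9 and 5.4 TPM in WT.

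The title of the series names TRIM13, a ubiquitin ligase of the endoplasmic reticulum membrane, as a gene repressed by CHAF1B. Trim13 (chromosome 14, 61598226 to 61610287) was at 7.40 ± 0.90 TPM (SD, n = 3) in KO and 5.20 ± 0.26 TPM (SD, n = 3) in WT, a ratio of 1.42, with no overlap between the groups. Its log2 fold change was 0.43 (SE 0.10, limma adjusted p = 0.031), and the exact permutation p was 0.1. A larger log2 fold change than that of Trim13 was found for 1348 of the 1745 genes called higher in KO. The Trim13 gene overlaps Kcnrg and the long noncoding RNA gene Dleu2 in the RefSeq annotation, and whether reads were counted by strand is not given in the sources used here, so its value is uncertain. Dleu2, chosen after its values were seen because of this overlap, rose from 8.50 ± 1.18 to 18.2 ± 3.15 TPM (log2 fold change 1.01, limma adjusted p = 0.015). The call for Trim13 was lost under quantile normalization (log2 fold change 0.28, adjusted p = 0.057) and without KO replicate 2 (adjusted p = 0.113), KO replicate 3 (0.13), WT replicate 2 (0.093) or WT replicate 3 (0.111); over all alternatives run the adjusted p lay between 0.0094 and 0.13.

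Across the transcriptome, 13575 genes reached at least 1 TPM in at least 3 libraries and were tested. Of these, 2575 (19.0%) differed between KO and WT at an adjusted p under 0.05, with 1745 higher and 830 lower in KO. The genes called higher had a median log2 fold change of 0.70 and those called lower of -0.32. A log2 fold change of at least 1 in size was seen for 573 genes called higher and 6 called lower. Calls toward higher values lay mostly among weakly expressed genes: of the 5268 genes with a mean of 1 to 10 TPM, 1000 were higher and 70 lower, while of the 2054 genes with a mean of at least 100 TPM, 127 were higher and 275 lower. Higher calls made up 67.8% of all calls with the TPM as deposited and 43.9% under quantile normalization. The KO and WT values did not overlap for 5813 genes (42.8%), where chance gives 10% on average over all splits of the 6 libraries. Genes are not independent, so the share in a single split can lie far from this average.

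The 6 libraries were not equally alike within their groups, and the count of changed genes depended on which library was left out. Across tested genes, Pearson's r of log2(TPM + 1) was 0.998 between KO replicates 2 and 3 and 0.998 between WT replicates 2 and 3, but 0.991 between KO replicates 1 and 2 and 0.984 between WT replicates 1 and 2 (genes are not independent replicates). Between the groups, KO replicate 1 had an r of 0.984 with WT replicate 2 and 0.986 with WT replicate 3, as large as the 0.984 and 0.986 of WT replicate 1 with these libraries. Without WT replicate 1 the count was 4850, and without KO replicate 1 it was 3682, with 1619 lower. It was 109 without KO replicate 2, 25 without WT replicate 2 and 15 without WT replicate 3. Without KO replicate 3, limma called 0 genes, and 3381 had an unadjusted p under 0.05. Leaving out KO replicate 1 and WT replicate 1 together, an alternative chosen after seeing the data, gave 3859 higher and 3710 lower.

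**Figure D2:**
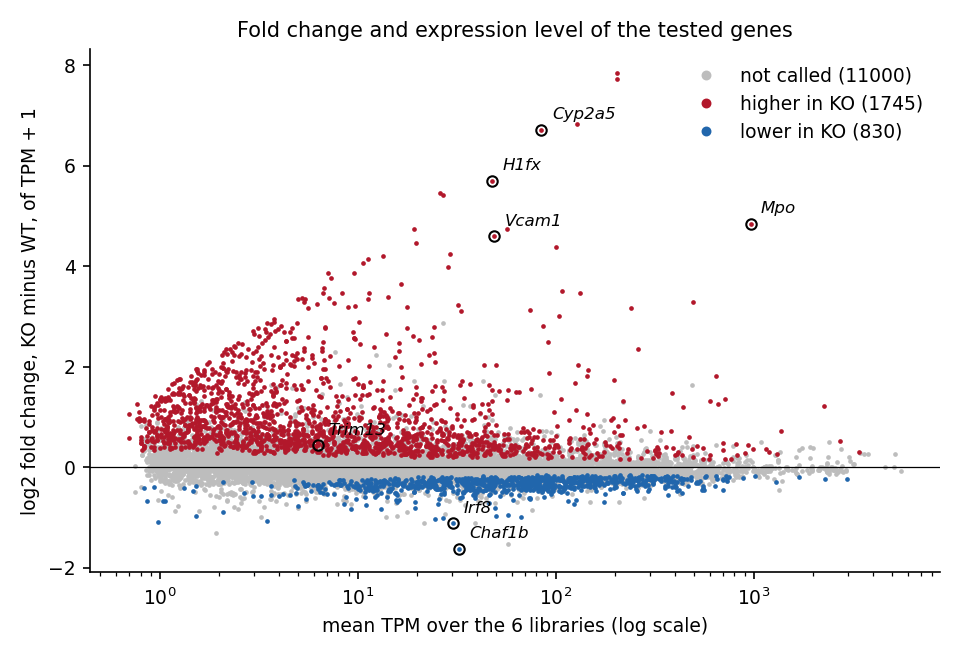
Log2 fold change, KO minus WT, on the log2(TPM + 1) scale (vertical axis) against the mean TPM over the 6 libraries (horizontal log axis) for the 13575 tested genes, with 1745 called higher in red, 830 called lower in blue and the rest in grey. Circles mark the 4 named genes with the largest rise, Chaf1b, Irf8 and Trim13, and most genes with large positive changes lie at low mean TPM.

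Among genes that met the conditions for naming, which leave out predicted and clone-derived models, most of the 10 largest rises started from a WT mean below 3 TPM. Cyp2a5, a cytochrome P450 enzyme (chromosome 7, 26835339 to 26843264), rose from 0.433 ± 0.115 to 169 ± 87.8 TPM (SD, n = 3; log2 fold change 6.71, SE 0.44, limma adjusted p = 0.0058). H1fx, a linker histone gene (chromosome 6, 87980421 to 87981482), rose from 0.80 ± 0.44 to 94.2 ± 29.5 TPM (log2 fold change 5.70, SE 0.28, adjusted p = 0.0058). Mpo, the myeloperoxidase of neutrophil primary granules (chromosome 11, 87793784 to 87804412), rose from 76.9 ± 54.4 to 1854 ± 725 TPM (log2 fold change 4.84, SE 0.71, adjusted p = 0.015). Vcam1, an adhesion molecule (chromosome 3, 116110020 to 116129688), rose from 2.57 ± 1.04 to 95.1 ± 52.6 TPM (log2 fold change 4.59, SE 0.52, adjusted p = 0.012). The other 6 of these 10 genes were Usp17lc, Olfml2b, Usp17ld, Lipn, Pf4 and Fam167b, with log2 fold changes from 4.47 down to 3.99. Usp17lc and Usp17ld belong to a family of near-identical copies, so the division of reads between them is uncertain. Cyp2a4, of the same family as Cyp2a5 and also on chromosome 7, was called higher by a log2 fold change of at least 1 too. Whether Cyp2a4 and Cyp2a5 share reads was not tested. In all 10 genes KO replicate 1 had the lowest KO value, such as 69.5 TPM for Cyp2a5 against 235 and 202 TPM in KO replicates 2 and 3.

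Falls under the same conditions were smaller. After Chaf1b, the largest was in Irf8 (chromosome 8, 120736358 to 120756694), a transcription factor of the monocyte and dendritic lineages, which fell from 41.3 ± 4.67 to 19.2 ± 6.96 TPM (SD, n = 3; log2 fold change -1.11, SE 0.23, limma adjusted p = 0.028). Aldh1l2, a mitochondrial enzyme of folate metabolism, fell from 5 ± 1 to 1.93 ± 1.10 TPM (log2 fold change -1.08, adjusted p = 0.040). Cd244, an immune receptor, fell from 36.7 ± 13.1 to 17.3 ± 4.86 TPM (log2 fold change -1.02, adjusted p = 0.049). Pck2, the mitochondrial phosphoenolpyruvate carboxykinase, fell from 75.3 ± 9.48 to 39.7 ± 14.9 TPM (log2 fold change -0.96, adjusted p = 0.044). F2rl2, Angpt1, Gss, Wdr34 and the small nucleolar RNA Snord57 fell by 0.98, 0.84, 0.84, 0.80 and 1.00 on the log2 scale. Snord57 lies inside a host gene and is shorter than the reads, so its value is uncertain.

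**Figure D3:**
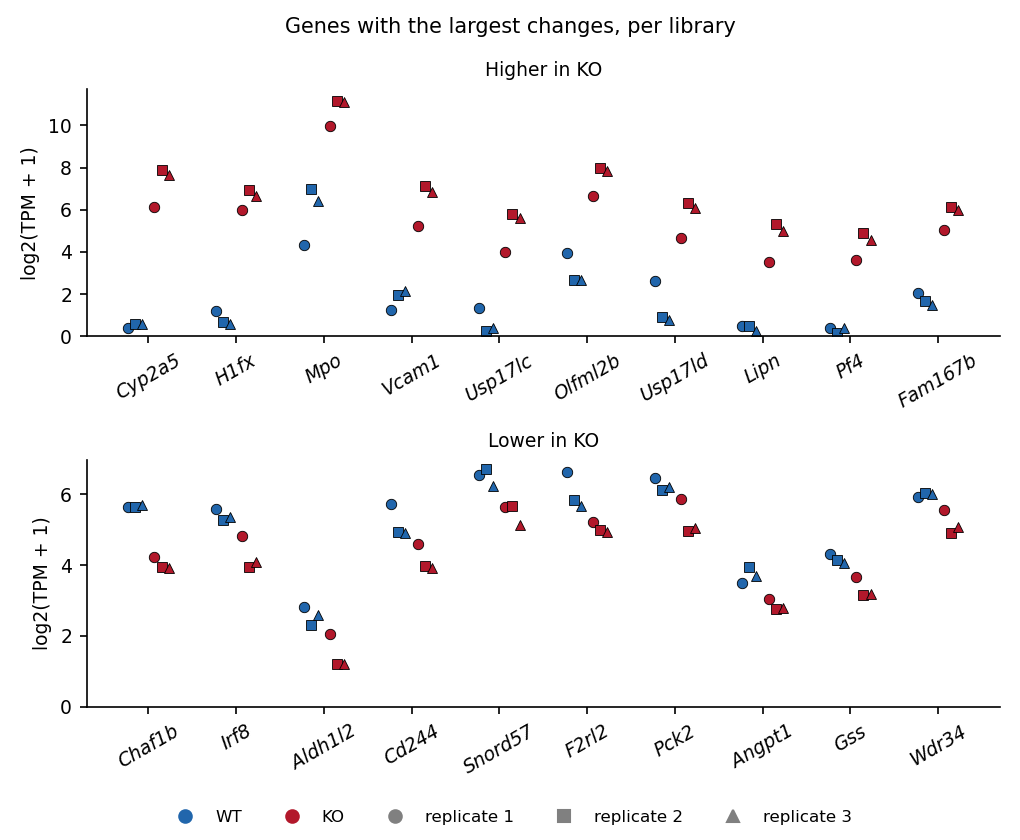
Log2(TPM + 1) per library (vertical axes) of the 10 named genes with the largest rise and the 10 with the largest fall (horizontal axes), WT in blue and KO in red with 1 symbol per replicate. KO replicate 1 lies closer to the WT libraries than the other KO libraries do for all 10 rising genes, with Mpo at 1018 TPM in KO replicate 1 against 2311 and 2233 TPM.

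Gene groups were compared through 26 lists fixed before the data were examined, of which 25 had at least 5 tested members. Camera with a preset correlation of 0.01 called 9 lists, and 0 of the 25 were called when the correlation was estimated from these 6 libraries. Of the 540 distinct list members tested, 105 were higher and 36 lower. Without KO replicate 2 the number of members called was 14, without KO replicate 3 it was 0 (limma; all 540 were tested), and without WT replicate 2 or WT replicate 3 it was 3. Without WT replicate 1 it was 273.

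Genes of granules and of maturing myeloid cells were compared as 3 lists. Of 13 tested primary granule genes, 9 were higher and none lower (11 higher when adjusted over the list alone), with a median log2 fold change of 0.52. Elane, the neutrophil elastase gene, rose from 1359 ± 205 to 3162 ± 494 TPM (SD, n = 3; limma adjusted p = 0.013), Prtn3, which encodes proteinase 3, from 2236 ± 129 to 3223 ± 308 TPM (0.015), and Nkg7 from 92.8 ± 9.41 to 196 ± 44.2 TPM (0.018). Camera gave this list an adjusted p of 4.7e-05, and the adjusted p = 0.56 with an estimated correlation. Of 23 late granulocyte genes, 10 were higher and none lower (12 higher when adjusted over the list alone), with a camera adjusted p of 4.7e-05 and an adjusted p = 0.57 with an estimated correlation. By direction fry did not call this list (adjusted p = 0.082). S100a8 and S100a9, which encode the abundant calprotectin subunits of neutrophils, rose from 44.9 ± 6.8 to 436 ± 170 TPM and from 15.4 ± 5.17 to 199 ± 94.2 TPM (limma adjusted p = 0.011 and 0.013). Cd177 and Trem3 also rose, by 2.78 and 1.00 on the log2 scale. WT replicate 1 stood apart in part of this list: its TPM was 62.0 for Ly6g, 21.4 for Cxcr2, 14.9 for Mmp9 and 110 for Ngp, which is 25.3, 47.6, 16.6 and 6.07 times the mean of WT replicates 2 and 3. It was at least 2-fold above that mean for 6 of the 23 genes, and below it for Trem3, Olfm4 and Chil3. Mmp9 was not called with all libraries (log2 fold change -0.48, adjusted p = 0.70) and was higher without WT replicate 1 (0.54, adjusted p = 0.024). Without WT replicate 1, 21 of the 23 late granulocyte genes were higher. The list's median log2 fold change was 1.00 with all libraries, 0.65 without WT replicate 2 and 0.63 without WT replicate 3.

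Among 19 monocyte and macrophage genes, 6 were higher and 1 lower (8 and 2 when adjusted over the list alone), and 14 were higher without WT replicate 1. Fcgr1, a high-affinity Fc receptor, rose from 2.93 ± 0.32 to 24.7 ± 8.34 TPM (SD, n = 3; limma adjusted p = 0.011), and Mpeg1 from 4.97 ± 1.32 to 35.7 ± 15.3 TPM (0.014). Cd74, the invariant chain of MHC class II, rose by 1.79 and Ly6c2 by 0.36 on the log2 scale, while the member that fell was Irf8. The camera adjusted p was 0.021, and the adjusted p = 0.74 with an estimated correlation. It was 0.077 without WT replicate 2, 0.066 without WT replicate 3 and 0.054 without the filter on low values, against 0.00015 without WT replicate 1. By direction fry did not call the list (adjusted p = 0.16).

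Interferon-stimulated genes and NF-κB target genes were compared as lists of their own. Of 29 interferon-stimulated genes tested, 11 were higher and none lower (16 higher when adjusted over the list alone), with a median log2 fold change of 0.56, and without WT replicate 1 the number was 24. Cxcl10, a chemokine, rose from 2.53 ± 0.95 to 18.1 ± 4.01 TPM (SD, n = 3; limma adjusted p = 0.011) and Rsad2, an antiviral enzyme, from 0.50 ± 0.27 to 4.33 ± 1.70 TPM (0.015). Oasl2 and Parp14 rose by 1.27 and 0.65 on the log2 scale, with KO means of 1.80 and 4.27 TPM. Camera gave an adjusted p of 1.6e-06, and the adjusted p = 0.56 with an estimated correlation. Of 22 NF-κB target genes, 7 were higher and none lower (9 and 1 when adjusted over the list alone), and 14 were higher without WT replicate 1. Nfkbia, the inhibitor that NF-κB itself induces, rose from 79.9 ± 6.68 to 153 ± 9.24 TPM (limma adjusted p = 0.0093), Il1b from 0.20 ± 0.17 to 3.90 ± 1.49 TPM (0.013), and Rel and Nfkbie by 0.41 and 0.49 on the log2 scale. The camera adjusted p was 0.010, and the adjusted p = 0.56 with an estimated correlation. With the preset correlation it was 0.060 without KO replicate 1, 0.14 without the filter on low values and 0.00039 without WT replicate 1.

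The only list that camera called lower was ribosome biogenesis. Of its 31 tested members 17 were lower and none higher (23 lower when adjusted over the list alone), with a median log2 fold change of -0.34, and 29 were lower without WT replicate 1. Rrp9, a protein of the U3 small nucleolar ribonucleoprotein, fell from 77.9 ± 6.32 to 52.9 ± 5.65 TPM (SD, n = 3; limma adjusted p = 0.019), Nop16 from 186 ± 6.85 to 134 ± 15.4 TPM (0.021), and Mybbp1a from 457 ± 33.3 to 348 ± 25.9 TPM (0.025). Ltv1 fell by 0.36 on the log2 scale. Dkc1 was at 103 ± 3.81 TPM in KO and 101 ± 5.97 TPM in WT (0.76). Camera gave an adjusted p of 1.6e-09, and the adjusted p = 0.56 with an estimated correlation. By direction fry did not call the list (adjusted p = 0.072).

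Markers of lineages other than granulocytes and monocytes were compared too. Most of their genes stayed below the 1 TPM filter, and those that passed it moved up where called. Calls among weakly expressed genes of any kind mostly went the same way. Of all 5268 tested genes with a mean of 1 to 10 TPM, 1000 were higher and 70 lower. These lists were not compared with genes of like expression, so the direction is not particular to them. Of 8 erythroid markers 4 were higher and none lower (5 higher when adjusted over the list alone): Klf1, Gata1, Rhd and Car2, with KO means of 4.43, 3.50, 20.7 and 2.47 TPM against 1.67, 1.10, 3.37 and 0.633 TPM in WT. Camera gave an adjusted p of 0.017, and the adjusted p = 0.56 with an estimated correlation. Of 5 megakaryocyte markers 2 were higher (3 when adjusted over the list alone, 4 without WT replicate 1). These were Pf4, a platelet chemokine that went from 0.233 ± 0.115 to 21 ± 8.91 TPM (SD, n = 3; limma adjusted p = 0.0082), and Gp1bb, from 3.33 ± 1.17 to 8.47 ± 1.25 TPM (0.020). The camera adjusted p was 0.031, and the adjusted p = 0.56 with an estimated correlation. It was 0.064 without WT replicate 3 and 0.0067 without WT replicate 1. Of 6 B cell markers 4 were higher (5 when adjusted over the list alone): Igll1 and Vpreb1, which encode the surrogate light chain, Cd79b, and Cd79a, which was at 1.10 TPM in KO and whose log2 fold change of 0.42 turned to -0.12 under quantile normalization. Camera gave an adjusted p of 0.010, and the adjusted p = 0.56 with an estimated correlation; it was 0.090 without the filter on low values. The remaining lineage lists were not called by camera, while fry called those of dendritic cells and of T and NK cells by direction (both adjusted p = 0.028). Higher members numbered 2 of 9 for mast cells and basophils (Mcpt8 and Ms4a2), 2 of 3 for eosinophils (Cebpe and Siglecf; too few for camera), 3 of 7 for dendritic cells (H2-Aa, H2-Eb1 and Cd74), 2 of 5 for T and NK cells (Prf1 and Thy1) and 3 of 6 for stromal and endothelial cells (Col1a1, Acta2 and Thy1), with the same numbers when adjusted over the list alone except 3 for T and NK cells. None of these 5 lists had a lower member. In the dendritic cell list H2-Ab1, an MHC class II gene, was at 36, 21.5 and 20.2 TPM in KO replicates 1, 2 and 3 and at 124.2, 20.9 and 26.3 TPM in WT replicates 1, 2 and 3 (log2 fold change -0.69, limma adjusted p = 0.48). Its log2 fold change was 0.09 without WT replicate 1. Without WT replicate 1, camera called the T and NK cell (adjusted p = 0.038), dendritic cell (0.041) and stromal and endothelial lists (0.011). Without KO replicate 2 it also called these 3 lists (0.049, 0.046 and 0.049), and without KO replicate 1 the stromal list (0.044), when 4 mast cell and basophil genes were higher. Without the filter on low values the T and NK cell (0.017) and stromal lists (0.038) were called, the latter also under quantile normalization (0.038). These calls used the preset correlation. With all libraries and an estimated correlation, the camera adjusted p was 0.56 for the T and NK cell, dendritic cell and stromal lists.

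**Figure D4:**
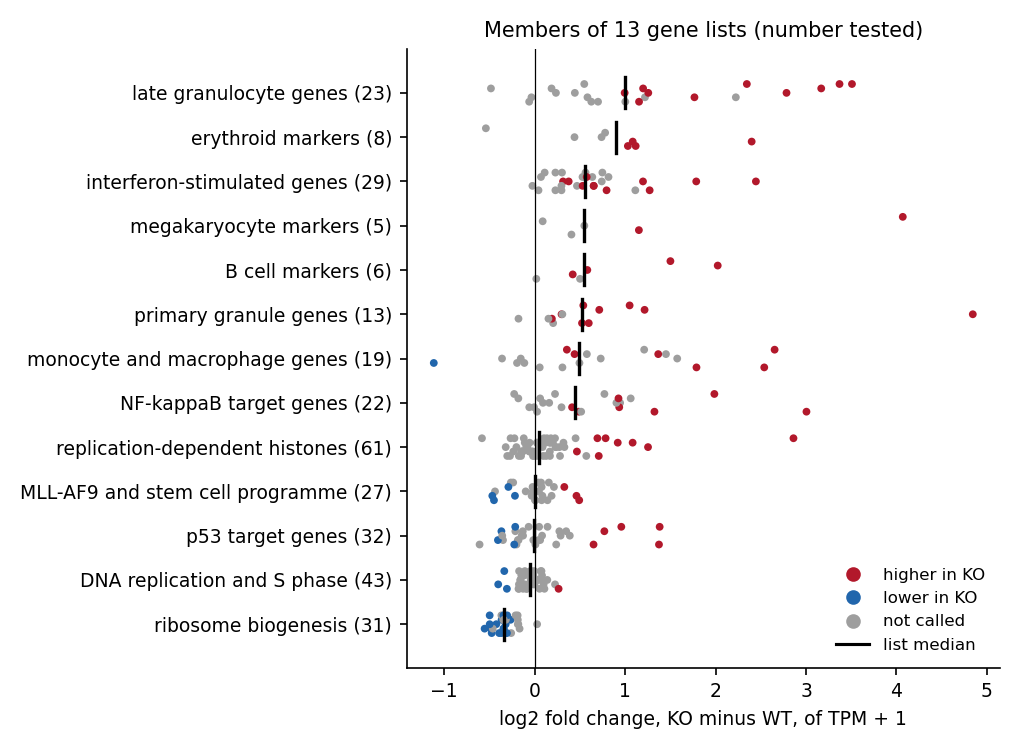
Log2 fold change, KO minus WT, on the log2(TPM + 1) scale (horizontal axis) of each tested member of 13 lists (vertical axis), red where called higher, blue where called lower and grey where not called, with a black line at the list's median. Medians run from -0.34 for ribosome biogenesis to 1.00 for late granulocyte genes (0.65 without WT replicate 2 and 0.63 without WT replicate 3).

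Genes of proliferation and chromatin assembly mostly did not pass the test. Of 43 DNA replication and S phase genes 3 were lower, namely Pold1, Pold2 and Cdt1, which fell by 0.31, 0.40 and 0.33 on the log2 scale, and 1 was higher, the thymidine kinase gene Tk1 (log2 fold change 0.27). The count was 2 lower and 1 higher when adjusted over the list alone, the camera adjusted p was 0.057, and 20 were lower without WT replicate 1 (camera adjusted p = 3.2e-05). Without the filter on low values camera also called this list lower (0.0020), as well as the lists of DNA repair (0.023) and of CAF-1 and other histone chaperones (0.0076). The medians of these lists were the same with and without the filter. The median over all tested genes was 0.0065 with it and 0.046 without it, so the genes they were compared with stood higher. Of 36 G2 and mitosis genes 2 were higher, Nusap1 and Dlgap5 (1 when adjusted over the list alone; camera adjusted p = 0.96; median -0.0041, mean 0.03; medians 0.0047, 0.052 and 0.036 without KO replicate 3, WT replicate 2 and WT replicate 3), but without WT replicate 1 camera called the list lower, with 6 lower and 2 higher members (adjusted p = 0.036). The DNA repair list had 1 lower member of 30, Parp1, which fell from 224 ± 3.2 to 168 ± 15.6 TPM (SD, n = 3; limma adjusted p = 0.018), also when adjusted over the list alone. Its camera adjusted p was 0.21, and 0.0014 without WT replicate 1, where 8 members were lower. Among 25 genes of CAF-1 and other histone chaperones the member called lower was Chaf1b itself (1 also when adjusted over the list alone; camera adjusted p = 0.079), with 9 lower without WT replicate 1 (0.0053) and 3 without KO replicate 1. Of 61 replication-dependent histone genes 8 were higher and none lower (4 when adjusted over the list alone; camera adjusted p = 0.17, and 0.033 without WT replicate 1). Examples were Hist1h4i, from 49.9 ± 5.90 to 87.4 ± 15.5 TPM (limma adjusted p = 0.023), and Hist1h1a and Hist1h3a, which rose by 0.71 and 0.69 on the log2 scale. Histone genes are near-identical in part and many of their transcripts lack a poly(A) tail, so these values are uncertain.

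The MLL-AF9 and stem cell list moved both ways. Of 27 tested members 4 were lower and 3 higher (5 and 3 when adjusted over the list alone; camera adjusted p = 0.90, direction down; median 0.0084, mean -0.0043), and 6 were lower and 5 higher without WT replicate 1 (median -0.039, and -0.0074 without KO replicate 1). Hoxa9 and Hoxa10, homeobox genes that MLL fusions activate, fell from 213 ± 8.47 to 174 ± 11.2 TPM (SD, n = 3; limma adjusted p = 0.029) and from 193 ± 4.67 to 166 ± 8.80 TPM (0.039). Myc fell from 107 ± 2.36 to 77.2 ± 9.76 TPM (0.024) and Bcl2 fell by 0.45 on the log2 scale (0.040). Zeb2 and Sox4 rose by 0.46 and 0.49 on the log2 scale. Of 33 myeloid transcription factors 10 were higher and 1, Irf8, was lower (11 and 2 when adjusted over the list alone; camera adjusted p = 0.057). Without WT replicate 1, 16 were higher and the camera adjusted p was 0.0017, and it was 0.046 without KO replicate 2, 0.011 with a mean of at least 5 TPM and 0.0071 under quantile normalization. With all libraries and an estimated correlation the camera adjusted p was 0.86. Cebpe, a factor of late granulocyte differentiation, rose from 264 ± 42.5 to 610 ± 108 TPM (limma adjusted p = 0.014). Gfi1b rose from 0.267 ± 0.462 to 12.1 ± 6.84 TPM (0.015), and Ets1 and Fli1 rose by 0.64 and 0.53 on the log2 scale.

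Stress and death pathways were mixed. Of 32 p53 target genes 5 were higher and 4 lower (7 and 6 when adjusted over the list alone; camera adjusted p = 0.90, direction down; median -0.0018, mean 0.10), with 10 higher and 6 lower without WT replicate 1. The median was 0.018, 0.0086 and 0.014 without KO replicate 1, KO replicate 3 and WT replicate 2. Btg2 rose from 14.9 ± 0.58 to 26.3 ± 2.48 TPM (SD, n = 3; limma adjusted p = 0.011) and Gdf15 from 0.367 ± 0.058 to 2.6 ± 0.625 TPM (0.011), while Xpc and Fdxr fell by 0.22 and 0.37 on the log2 scale. In the Bcl-2 family and caspase list 3 of 28 were higher, among them Bcl2l2, and 1 was lower, Bcl2 (the same numbers when adjusted over the list alone; camera adjusted p = 0.40), and without WT replicate 1 the numbers were 9 and 3. Of 32 ER stress and amino acid response genes 10 were higher and 5 lower (12 and 8 when adjusted over the list alone; camera adjusted p = 0.61; median 0.03, mean -0.05). Without KO replicate 1, 8 were lower, and the median was 0.12 without WT replicate 1 and -0.028 without WT replicate 2. The higher ones included Dnajb9, Creld2 and Manf, which encode proteins of endoplasmic reticulum folding and rose by 0.42, 0.41 and 0.22 on the log2 scale, and the lower ones Mthfd2 and Shmt2, enzymes of mitochondrial folate metabolism, which fell by 0.67 and 0.41. Among 22 immediate early and heat shock genes 3 were higher, Btg2 and the near-identical copies Hspa1a and Hspa1b, whose division of reads is uncertain (3 also when adjusted over the list alone; camera adjusted p = 0.96; median -0.03, mean 0.34), and without WT replicate 1, 6 were higher and 5 lower, with a median of 0.15. Of 11 oestrogen response genes 2 were higher and none lower (2 also when adjusted over the list alone; camera adjusted p = 0.58), and 5 were higher without WT replicate 1. The 2 genes called with all libraries were Igfbp4 and the oestrogen receptor gene Esr1. Igfbp4 rose from 202 ± 10.5 to 572 ± 141 TPM (limma adjusted p = 0.013) and Esr1 from 19.7 ± 0.44 to 26.4 ± 1.37 TPM (0.015). The CreERT2 carried by all these cells holds part of an oestrogen receptor. Whether its reads were counted for Esr1 is not given in the sources used here, so this value is uncertain.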

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

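The tests of depth and of genomic DNA below were chosen after the result was seen. Genes left out of the test because they did not reach 1 TPM in 3 libraries were still listed more often in KO. Of these 22294 genes, 6196, 7427 and 7132 were above 0 TPM in KO replicates 1, 2 and 3, against 4516, 4525 and 4541 in WT replicates 1, 2 and 3. Over all genes, 20488 ± 642 were above 0 in KO and 18052 ± 15.9 in WT (SD, n = 3; exact permutation p = 0.1, the smallest possible).

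Deeper sequencing of the KO libraries lists more genes at very low values, but would not carry many genes from 0 to 1 TPM in one group alone. There were 76 genes at 0 in all WT libraries and at 1 TPM or more in at least 2 KO libraries, and 0 genes the other way round, which argues against depth for this part. Another 849 genes were above 0 in all KO libraries, at 0 in all WT libraries and below 1 TPM throughout; for these, depth cannot be told apart from expression, since TPM keeps no depth. Genomic DNA should list odorant and vomeronasal receptor genes about as often as other genes. Yet 5 of 1346 such receptor genes at 0 in all WT libraries were above 0 in all KO libraries (0.371%). This held for 546 of 5833 other protein-coding genes at 0 in all WT libraries (9.36%), a ratio of 0.0397 (Fisher's exact p = 8.5e-44). Genes above 0 in only some KO libraries were not counted as listed. Release of silent genes after loss of Chaf1b, and an effect of β-estradiol itself, remain open as untested explanations.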

How the results depend on the processing

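Leaving out KO replicate 1 and WT replicate 1 together, and leaving out microRNA and small nucleolar RNA genes (2693 called), were chosen after the result was seen. Under quantile normalization 2555 of the 2575 called genes kept their sign, and 1933 of them were among the 3068 genes called there. Pseudocounts, median-ratio scaling and eBayes without trend or robust gave 2257 to 2888 genes. The count was 1578 (883 higher) with a mean of at least 5 TPM, where fewer genes were tested, 579 with a log2 fold change of at least 1, and 7569 (3859 higher, 3710 lower) without KO replicate 1 and WT replicate 1 together, where 2558 of the 2575 were called. Without a filter 2730 were higher, and under quantile normalization 1722 were lower; the cause was not tested. Leaving out 1 library each gave 0 (without KO replicate 3; limma, with 3381 at an unadjusted p under 0.05) to 4850 genes (without WT replicate 1), with 0 to 2927 higher and 0 to 1923 lower. The cause was not tested.

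Same-numbered KO and WT samples did not deviate together (correlations -0.20, -0.15 and -0.16), and no sample correlated best with its own number. With the replicate number as a block 333 genes were called (300 higher, 33 lower), and Trim13 was 0.43 (adjusted p = 0.080).

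Leaving out 1 library each, Chaf1b lay between -1.72 and -1.57 and Trim13 between 0.36 and 0.51, with Trim13 at 0.28 under quantile normalization, where Cd79a was -0.12. Mmp9 lay between -1.03 and 0.54 (the latter without WT replicate 1) and was 0.61 without both libraries, since WT replicate 1 alone held it high. Camera called 7 to 18 lists without 1 library (18 without WT replicate 1), 15 without both, 12 without a filter, 7 with a mean of at least 5 TPM, 11 under quantile normalization and 0 with an estimated correlation. Fry called 8 by direction and 22 in either direction. By direction it did not call ribosome biogenesis (adjusted p = 0.072), late granulocyte genes (0.082) or monocyte and macrophage genes (0.16), which camera called. It called the dendritic cell and the T and NK cell lists (both 0.028), which camera did not call in the main comparison. The median of the G2 and mitosis list lay between -0.072 (without WT replicate 1) and 0.052 without 1 library each and was -0.093 without both. Among named genes, 83, 100, 95 and 96 lost their call without KO replicate 2, KO replicate 3, WT replicate 2 and WT replicate 3, with their direction kept, and 66 with the block. Depth is unknown, which limits what values below 1 TPM can show.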

Other observations

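The tests of KO replicate 1, of WT replicate 1 and of protein-coding neighbours alone, and the counts by gene class, were chosen after the result was seen, as were the genes named here. Long noncoding RNA genes were called higher more often than protein-coding genes: 344 of 1263 (27.2%; 31 lower) against 1211 of 10539 (11.5%; 721 lower). Draws of protein-coding genes of like mean expression gave 233 on average and 277 at most (permutation p = 0.0001, the smallest that 10000 draws can give). The class median was 0.19, but -0.03 under quantile normalization, with 237 higher and 114 lower. Protein-coding genes had a median of -0.0095, and of -0.07 under quantile normalization, with 974 higher and 1438 lower of 10539. The largest rises of all tested genes were in the noncoding genes 1700020D14Rik (log2 fold change 7.84) and Gm29089 (7.73), both on chromosome Y, whose nearly equal TPM of 406 and 408 in KO leave it uncertain whether they share reads.

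Among 38 tested genes with a Trim symbol, 11 were higher and 2 lower, and 4 and 2 under quantile normalization. Trim30a and Trim6 rose by 0.65 and 0.59 on the log2 scale (limma adjusted p = 0.022 and 0.021). Genes listed at 0 in all WT libraries included Csn2, the β-casein gene (8.4, 18.3 and 15.8 TPM in KO replicates 1, 2 and 3), the olfactory cytochrome gene Cyp2g1 (5.2, 20.9 and 17.8 TPM) and Vat1l (4.7, 13.8 and 11.4 TPM). Small nucleolar RNA genes had 10 lower and 0 higher of 108 tested (limma), with a median of -0.27, beside 830 lower of all 13575 tested genes. Their share of TPM was 0.566, 0.524 and 0.519% in KO replicates 1, 2 and 3 and 0.516, 0.827 and 0.704% in WT replicates 1, 2 and 3 (exact permutation p = 0.4), so WT replicate 1 lay below every KO library. The limit given for Snord57, a host gene and a length below that of the reads, may hold for others of this class, so these values are uncertain.

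Of the 10 splits of the 6 libraries into 3 and 3, 1 gave 2575 genes, the real one, and the highest of the others gave 0 (limma, with 2373 at an unadjusted p under 0.05 for the split of KO replicate 1, WT replicate 2 and WT replicate 3 against the rest); so few splits cannot give a share under 0.1.

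KO replicate 1 lay between the WT libraries and KO replicates 2 and 3. Over 714 genes called higher by a log2 fold change of at least 1 in the fit without KO replicate 1, its TPM was a median of 42.5% of the way from the WT mean to the mean of KO replicates 2 and 3 (5th to 95th percentile 26.8 to 66.3%), and over 262 genes called lower by at least 0.5 in that fit, without Chaf1b, 49.0%. A share of undeleted cells or WT RNA would put Chaf1b at the same point, but Chaf1b lay at 90.3% of the way, which argues against it as the whole cause. A later response to the deletion in the cells of that library may be a candidate explanation, which was not tested.

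WT replicate 1 held some late granulocyte genes at high levels: 6 of 23 were at least 2-fold above the mean of WT replicates 2 and 3. The median over those 6 alone was 20.9-fold, and they include Ly6g, Cxcr2, Mmp9 and Ngp. The other genes of the list were under 2-fold, and Trem3, Olfm4 and Chil3 lay below that mean, at 0.90, 0.14 and 0 times it. Mature neutrophils as the source would bring their abundant S100a8 and S100a9, but these were 1.18-fold and 1.72-fold (TPM 50 and 21.4), which argues against it. Another RNA extraction or library preparation cannot be told apart from a state of these cells: the mitochondrial share was 2.37% against 3.59 to 3.94% in the other libraries, and the small nucleolar RNA share 0.516% against 0.519 to 0.827%. The design names no biological difference between WT replicate 1 and the other WT libraries.

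Genes that rose may lie next to each other. Among 510 placed genes higher by a log2 fold change of at least 1, 68 adjacent pairs without a shared symbol stem were both risen, against 21 on average and 38 at most in 10000 shuffles (permutation p = 0.0001, the smallest possible). Among protein-coding genes alone, 26 pairs were seen against 11.7 on average and 27 at most (permutation p = 0.0002), such as Elane with Cfd, Igll1 with Vpreb1 and Vat1l with Clec3a. Leaving out shared symbol stems did not remove all related or overlapping neighbours. Igll1 and Vpreb1 both encode the surrogate light chain, and Ang and Rnase4 start at the same position, 51091077 on chromosome 14. The excess is therefore not shown for unrelated genes. Neighbours in one genomic region can share regulation or unannotated read-through, which this test does not separate.

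Single-exon genes may rise more often than genes with introns. Of 187 single-exon protein-coding genes, 17 (9.09%) rose by a log2 fold change of at least 1, against 340 of 10282 others (3.31%), and matched draws gave 7.23 on average and 18 at most (permutation p = 0.0008). Genes whose symbol did not match the RefSeq table, among them the histone genes Hist1h4i, Hist1h1a and Hist1h3a, are not in these counts. These 17 include Hspa1a and Hspa1b, near-identical copies, and 3 Ttc30 genes, so they are not all independent.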
